A study of Homo sapiens with 3 samples.

How the data were processed

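RNA-seq of the human leukaemia cell line MV-4-11 was analysed in 3 libraries, with 1 library per group. Per the labels, the groups were untreated cells cultured for 1 day and cells given FL-Fc-DM1 at 0.5 nM or 1.5 nM for 1 day. Polyadenylated RNA was captured on oligo(dT) beads, fragmented, copied with random primers and sequenced on an Illumina instrument, per the labels' protocols.

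The authors deposited 1 table of 20332 genes that gives an estimated count and a TPM value for each gene in each library. The estimated counts were deposited without normalisation, and 12.7% of them in the control, 12.3% in the 0.5 nM and 12.0% in the 1.5 nM library were not whole numbers. The deposited TPM values are scaled to gene length and sum to 1000000 in each library. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR were used. The role of each tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The table's columns carry the numbers 0, 1 and 2 after the drug's name. These were read as control, 0.5 nM and 1.5 nM; the table itself does not print the doses, so that reading of the 2 treated columns rests on the order of those numbers. If the treated columns stood the other way round, every statement on the 2 doses would be exchanged.

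Gene symbols were taken from the table, which gives them for 19715 genes and an identifier alone for 617. List members were matched through the table's symbols and through older symbols from a gene name table. Transcript GC content came from GENCODE release 29 and was found for 11252 (99.4%) of the 11322 genes analysed.

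Estimated counts were rounded to whole numbers. Genes with a mean of 1 or more CPM, counts per 1000000 counts, over the 3 libraries were kept, which left 11322 genes. Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.987 for the control, 1.006 for the 0.5 nM and 1.008 for the 1.5 nM library. Log2 CPM values were computed with a prior count of 2, and the log2 ratio of a gene is the difference between 2 libraries. Genes with an absolute log2 ratio of 1 or more were counted as higher or lower. Ratios and lists were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the log2 CPM values differed from those of edgeR by at most 5e-07.

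With 1 library per group there was no spread between replicates, so the planned edgeR quasi-likelihood test, camera and all adjusted p-values were not run, and no difference has a replicate check. The ratios compare these libraries, not the conditions. Each named gene has an exact 95% interval of its ratio (Clopper-Pearson, from the 2 counts). These intervals and the floor of 3 counts, used where a library had 0 counts, cover counting error only, and PCR copies are not independent molecules. The floor of 3 counts equals 0.136 CPM in the control, 0.182 CPM in the 0.5 nM and 0.177 CPM in the 1.5 nM library. The depth was 22329953 estimated counts in the control, 16427206 in the 0.5 nM and 16864857 in the 1.5 nM library.

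Before the data were examined, 32 gene lists were fixed. All are in the counts of lists, and 1 of them is not reported here. For each list, the median log2 ratio of its measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile and the central 95% of the random medians are given as a description of these libraries. Libraries of unchanged genes were simulated 100 times with Poisson counts at the real depths, which gives the number of genes that counting error alone would place past the threshold. The simulation holds no variation between cultures. KEGG pathways as annotated in the deposited table were treated in the same way with 1000 random lists each.

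The rule for named genes was also fixed beforehand. It takes FLT3 first. For each dose against the control it takes the 10 largest ratios in each direction among genes past the threshold with a symbol and a mean of 5 or more CPM, and for 1.5 nM against 0.5 nM the 5 largest. From each list it takes up to 4 measured members with the largest absolute ratio at 1.5 nM. It always takes CDKN1A, TUBB, TUBA1B, CCNB1, PLK1, MKI67, MYC, HOXA9, MEIS1, KIT and ABCB1. Other genes that are named, DSP and DSG2 among them, were chosen after their values were seen. Genes with a count that was not whole in any library were taken to share reads with another gene and are called uncertain. The sources used here do not say why counts are not whole, so shared reads are an inference wherever they are named. Uncertain genes were 2510 (22.2%) of the genes analysed.

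The steps were tested on simulated counts for 1.5 nM against control. In that set, of about 11300 genes, all 50 genes made 4-fold higher and all 50 made 0.25-fold were counted, as were 48 of 50 at 2.5-fold and 47 of 50 at 0.4-fold, and 6 unchanged genes were counted in error. Of 100 lists of 25 unchanged genes, 6 lay beyond the central 95% of random lists. All 100 lists shifted by 0.3 on the log2 scale lay above it. Genes in that simulation vary independently, so these shares are no error rates for lists whose genes move together between cultures.

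Alternatives fixed beforehand were DESeq2 1.42.0 size factors, library totals alone, no expression minimum beyond removing genes at 0, a minimum mean of 5 CPM, a prior count of 5, log2(TPM + 1) values, and totals without the mitochondrially encoded, ribosomal protein and haemoglobin genes (109 genes). Chosen after seeing the data were removal of the trend of the ratio with GC content (20 bins), random lists matched on GC content as well, both of these together, genes with whole counts alone, ratios whose counting interval leaves out 0, and leaving out genes nearly missing from 1 library.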

Results

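MV-4-11 is an acute leukaemia line with a KMT2A rearrangement and an internal tandem duplication of FLT3, the receptor of FLT3 ligand. The treatment, FL-Fc-DM1, joins FLT3 ligand and an antibody Fc part to DM1, a maytansinoid that binds tubulin and blocks microtubule assembly. The series asks how the transcriptome of these cells differs between untreated cells and cells given the conjugate for 1 day at 0.5 nM or 1.5 nM. Each of the 3 groups has 1 library, with 22329953 estimated counts in the control, 16427206 in the 0.5 nM and 16864857 in the 1.5 nM library. Mitochondrially encoded genes held 5.36%, 5.07% and 5.31% of the counts in that order. The dose of each treated library was read from the number in its column name. No value has a replicate behind it, and intervals in brackets are exact 95% intervals for counting error only.

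FLT3 is the receptor that the ligand part of the conjugate binds. FLT3 (ENSG00000122025) stood at 506.5 CPM in the control, 489.6 CPM in the 0.5 nM and 448.7 CPM in the 1.5 nM library. Its log2 ratio to the control was -0.05 [-0.09, -0.01] at 0.5 nM and -0.17 [-0.22, -0.13] at 1.5 nM. Within the list of FLT3 and its signalling partners, the median of 20 measured genes was 0.05 at 0.5 nM and 0.02 at 1.5 nM, inside the central 95% of random lists at both doses. With the GC trend removed and lists matched on GC content, the 0.5 nM median of 0.07 lay above the random range of -0.08 to 0.05, and the 1.5 nM median stayed inside. AXL, a receptor tyrosine kinase, had log2 ratios of 0.74 and 1.17, and the kinase SRC had 0.82 and 1.02. The STAT5 and PIM targets had medians of -0.04 and 0.10, also inside the random range, with PIM1 at -0.29 and SOCS2 at -0.28 in the 1.5 nM library.

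At 0.5 nM against the control, p53 target genes stood higher and ribosomal protein and DNA replication genes slightly lower. CDKN1A (ENSG00000124762), which encodes the cyclin-dependent kinase inhibitor p21, was at 31.8 CPM against 11.7 CPM in the control, a log2 ratio of 1.43 [1.22, 1.66]. The histone gene H2AC6 had the largest ratio of the genes named by size, 1.62 [1.22, 2.09]. The haem-degrading enzyme gene HMOX1 (ENSG00000100292) had 1.33 [1.00, 1.70], and CYP1B1, a cytochrome P450 gene, had 1.29 [1.13, 1.46]. The pre-B-cell receptor component gene IGLL1 was lower, at 9.2 CPM against 19.8 CPM, a log2 ratio of -1.10 [-1.39, -0.84].

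In all, 60 genes were at least 2-fold higher and 26 at least 2-fold lower in the 0.5 nM library, against means of 3.0 and 3.91 in simulated unchanged libraries. The other genes with the largest increases were the growth factor gene IGF1 with 1.28, PHLDA1 with 1.11 and the complement gene C3 with 1.09. IL4I1, which encodes an amino acid oxidase, had 1.42, C8orf44-SGK3 had 1.28 and the receptor gene TLR6 had 1.11, and these 3 are uncertain because they share reads with other genes. IGLL1 was the only lower gene with a symbol and a mean of 5 or more CPM. Of the 26 lower genes, 18 share reads with another gene, and the count was 8 with whole-count genes alone. Simulated unchanged libraries reached at most 8 lower genes, over all genes.

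At 0.5 nM, 16 of the 32 gene lists lay beyond the random range, 9 of them higher and 7 lower. Of the 28 measured p53 targets, 26 lay above 0 in the 0.5 nM library, and their median of 0.29 was above 100% of the random lists (random range -0.08 to 0.09). FAS, which encodes a death receptor, had 1.14, BTG2 had 1.04, TP53INP1 had 0.96 and MDM2, the ubiquitin ligase that acts on p53, had 0.56. Immediate early and AP-1 genes had a median of 0.23, with 16 of 20 above 0, and JUN at 0.97. The NF-kB and inflammatory genes had a median of 0.19 with 15 of 20 above 0, and the type I interferon response genes 0.22 with 22 of 26 above 0. Smaller shifts beyond the random range were 0.15 for the NRF2 oxidative stress genes, 0.15 for the monocyte and macrophage markers and 0.14 for the drug efflux and conjugate processing genes. The MAPK output and feedback genes had 0.22 and the replication-dependent histone genes 0.66, the latter over 8 genes that largely lack poly(A) tails.

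All 41 measured S phase and DNA replication genes lay below 0 in the 0.5 nM library, with a median of -0.16 (random range -0.06 to 0.04). All 40 cytosolic ribosomal protein genes did so too, with a median of -0.15. Among the MYC targets and ribosome biogenesis genes, 25 of 30 lay below 0, with a median of -0.11, and MYC had -0.21. Oxidative phosphorylation genes had -0.10, mitochondrially encoded genes -0.12 and tubulin genes -0.17. Granulocyte markers had -0.19, with CTSG at -0.56 and PRTN3 at -0.42, and their median of -0.10 with the GC trend removed lay inside the GC-matched random range. The ratios at 0.5 nM were lower for genes of higher transcript GC content (Spearman -0.27 across genes; genes are not independent replicates). The tenth of genes with the lowest GC content had a median of 0.09 and the tenth with the highest -0.09.

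At 1.5 nM against the control, oxidative stress, inflammatory and macrophage genes stood higher and DNA replication genes lower. HMOX1 was at 37.9 CPM against 4.7 CPM, a log2 ratio of 2.97 [2.70, 3.32]. C3 had 2.40 [2.01, 2.91], and IL4I1, which shares reads with another gene, had 2.42. The most abundant tubulin genes, TUBB and TUBA1B, were lower. TUBB (ENSG00000196230) was at 1606 CPM against 2368 CPM, a log2 ratio of -0.56 [-0.58, -0.54], and TUBA1B (ENSG00000123416) was at 1445 CPM against 2094 CPM, a log2 ratio of -0.54 [-0.56, -0.51]. TUBA1B is uncertain because it shares reads with other genes, which its interval does not cover.

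A total of 166 genes were at least 2-fold higher and 65 at least 2-fold lower in the 1.5 nM library, against means of 2.85 and 3.62 in simulated unchanged libraries. Further genes with large increases were H2AC6 with 1.76, IGF1 with 1.68, CYP1B1 with 1.67, PHLDA1 with 1.64, the semaphorin gene SEMA6B with 1.58 and the surface protein gene CD109 with 1.52. C8orf44-SGK3, which shares reads, had 1.66. CDKN1A was at 19.7 CPM, with a log2 ratio of 0.75 [0.51, 0.99].

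**Figure D1:**
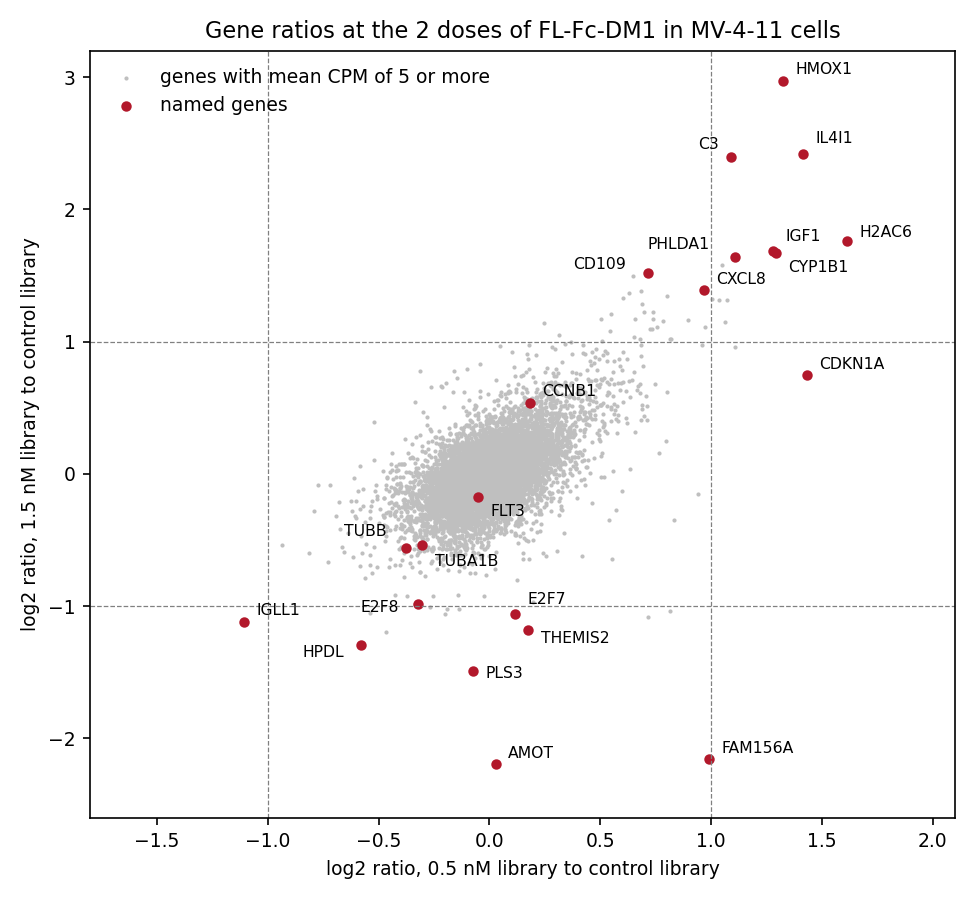
Each grey point is a gene with a mean of 5 or more CPM, placed by its log2 ratio to the control library at 0.5 nM (x axis) and at 1.5 nM (y axis), and red points are genes named in the text. HMOX1 lies at 1.33 and 2.97, CDKN1A at 1.43 and 0.75, and IRS4, at -6.57 on the y axis, lies outside the plot.

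The largest decreases at 1.5 nM included genes that the 0.5 nM library held at the control's level. IRS4, an insulin receptor substrate gene, had 224 counts in the control, 204 at 0.5 nM and 0 at 1.5 nM, which makes it at least 57.6-fold lower than in the control at a floor of 3 counts. AMOT, which encodes the junction protein angiomotin, had 157, 120 and 25 counts, a log2 ratio of -2.20 [-2.95, -1.66], and PLS3, which encodes an actin-bundling protein, had 278, 198 and 75 counts, a ratio of -1.49 [-1.90, -1.14]. These 3 genes stood beside a wider group. With whole counts in each library, 50 genes had 2 or fewer counts at 1.5 nM and 10 or more in each of the other libraries, against 3 such genes for the control and 1 for the 0.5 nM library. DSP and DSG2, desmosome genes of epithelial cells, are among them with 32 and 21 counts in the control and 0 at 1.5 nM.

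**Figure D2:**
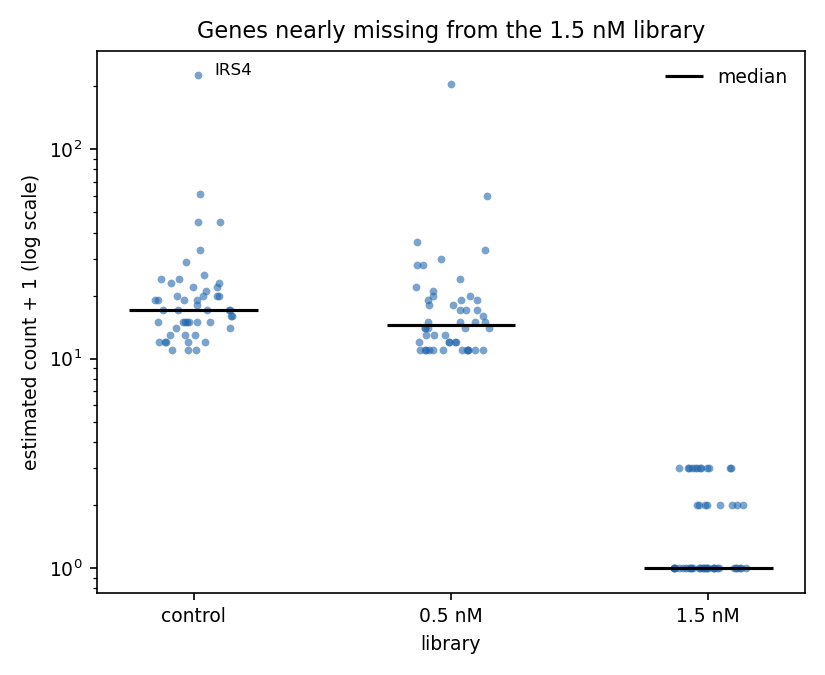
Estimated counts plus 1 (log scale) of the 50 genes with 2 or fewer counts in the 1.5 nM library and 10 or more in each of the other libraries, by library, with a bar at each median. IRS4 is the highest point, with 224 counts in the control and 204 in the 0.5 nM library; the gap to the 1.5 nM library is set by how the genes were chosen.

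Other genes with large decreases at 1.5 nM were HPDL with -1.29, THEMIS2, an immune signalling gene, with -1.18 [-1.41, -0.97], IGLL1 with -1.12, the cell cycle repressor gene E2F7 with -1.06 and the stress kinase gene MAP2K6 with -1.06. FAM156A had -2.16 and LHFPL5 had -1.20, and both share reads with other genes. Of the 65 lower genes, 29 share reads and 6 belong to the nearly missing group. The count was 36 with whole-count genes alone.

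At 1.5 nM, 14 of the 32 gene lists lay beyond the random range, 11 of them higher and 3 lower. All 41 measured S phase and DNA replication genes lay below 0 in the 1.5 nM library, with a median of -0.38 (random range -0.08 to 0.04). The transcription factor gene E2F8 had -0.98, the cyclin gene CCNE1 -0.73 and the DNA methylation factor gene UHRF1 -0.65, while none was 2-fold lower. CCNE2, which shares reads, had -0.92. The median with the GC trend removed was also -0.38.

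The mitosis genes were mixed. Their median of 0.06 over 46 genes lay just above the random range of -0.08 to 0.03, with 26 above and 20 below 0. CCNB1 (ENSG00000134057), the mitotic cyclin B1 gene, had 0.54 [0.48, 0.60], HMMR had 0.50, and PLK1, a mitotic kinase gene, had 0.40. TOP2A, which encodes a topoisomerase, had -0.61 [-0.64, -0.58], CDK1 had -0.51 and the proliferation marker MKI67 had -0.36.

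Among the 16 NRF2 oxidative stress genes, all lay above 0 at 1.5 nM, with a median of 0.33 (random range -0.13 to 0.08). OSGIN1 had 1.26, from 31 counts in the control and 60 at 1.5 nM. The cystine transporter gene SLC7A11 had 0.94 and ME1, which encodes malic enzyme, 0.79. Other members were closer to the control, with GCLC at 0.19, GCLM at 0.18 and TXNRD1 at 0.06. The ferritin heavy chain gene FTH1 had 0.93 and is uncertain. NF-kB and inflammatory genes had a median of 0.46, with 17 of 20 above 0. BIRC3 had 2.64, from 8 counts in the control and 48 at 1.5 nM, the adhesion receptor gene ICAM1 1.60, the chemokine gene CXCL8 1.39 and RELB 1.14. Monocyte and macrophage markers had a median of 0.35 over the 17 measured of 28 listed, with 13 above and 4 below 0. CD86, which encodes a co-stimulatory protein, had 1.51, from 35 counts in the control and 80 at 1.5 nM. The integrin gene ITGAX had 1.09 from 71 and 119 counts, and the integrin gene ITGAM had 0.90 from 47 and 69 counts. Type I interferon response genes had 0.28, with 22 of 26 above 0, and ranged from 1.42 for OAS1 to -1.08 for OAS3, both from 30 or fewer counts.

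Lysosome and autophagy genes had a median of 0.19 at 1.5 nM, with 27 of 29 above 0, including GABARAPL1 with 0.94. Drug efflux and conjugate processing genes had 0.19, with 8 of 9 above 0. That median equals the one of the lysosome list, which also holds LAMP1 and CTSB, so these lists are not independent. The neonatal Fc receptor gene FCGRT had 1.05 and the efflux pump gene ABCC1 0.50, while the pump gene ABCB1 had 2, 1 and 0 counts, too few for a ratio. Replication-dependent histone genes had 0.78 over 8 genes. MAPK output and feedback genes had 0.41, with 6 of 11 above 0. That median rests on its less expressed members, since it was -0.15 among genes with a mean of 5 or more CPM. Members named by size were PHLDA1 with 1.64, DUSP4 with 0.97, FOSL1 with 0.58 and ETV4 with 0.48. DUSP4 and ETV4 lie below that minimum. Lower members included SPRY2 with -0.45 and DUSP6 with -0.41. The 3 measured stromal and epithelial markers had 0.75, with PECAM1 at 0.78, KRT8 at 0.75 and KRT18 at -0.46. PECAM1 is also expressed by myeloid cells, and the median was inside the GC-matched random range.

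Lower medians at 1.5 nM beyond the random range were -0.10 for the MYC targets and ribosome biogenesis genes and -0.12 for the oxidative phosphorylation genes, with 27 of 28 below 0. MYC had -0.23. The tubulin genes as a list had -0.12, inside the random range. Less abundant members went both ways, with TUBA1A at 0.79, TUBB3 at 1.11 and TUBA8 at -1.09. These 3 share reads with other genes, as does TUBA1B. Among 23 microtubule regulators the median was -0.03, with MAP1A at -1.19 and TTC5, which acts in the decay of tubulin transcripts, at -0.40.

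The remaining lists lay inside the random range at 1.5 nM. The p53 targets had 0.03, with BTG2 at 1.32 and TP53INP1 at 0.97, and the immediate early and AP-1 genes had 0.07, with JUN at 1.11. The intrinsic apoptosis genes had 0.03, with BIRC3 at 2.64, BMF at 0.34, CASP8 at 0.33 and CASP2 at -0.45. The integrated stress and unfolded protein response genes had -0.04. Among them, SLC7A11 had 0.94 and ATF3 0.81, while CHAC1 had -0.93 and PHGDH, a serine synthesis gene, -0.78. The KMT2A fusion targets and leukaemia stem cell genes had -0.07. In that list HOXA10 had -0.49, HOXA9 -0.37, MEIS1 -0.22 and CD44 0.55. Heat shock and proteotoxic stress genes had -0.02, hypoxia and glycolysis genes 0.05, cholesterol biosynthesis genes -0.06, cytosolic ribosomal protein genes -0.01 and mitochondrially encoded genes -0.11. Polyploidy and tetraploidy response genes had -0.06, with CDKN1C at 1.83 from 10 and 32 counts and SASS6 at -0.54. Granulocyte markers had -0.09, megakaryocyte and erythroid markers 0.06 over 5 genes, and B and T lymphocyte markers 0.08 over 3 genes. KIT had 12, 19 and 22 counts and lay just under the expression minimum.

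The lists not yet given for 0.5 nM also lay inside the random range. The mitosis genes had 0.01, microtubule regulators -0.01, intrinsic apoptosis genes 0.00, integrated stress and unfolded protein response genes -0.04, heat shock genes 0.03, hypoxia and glycolysis genes -0.01 and cholesterol biosynthesis genes 0.00. KMT2A fusion targets had 0.01, megakaryocyte and erythroid markers 0.08, lymphocyte markers -0.15, stromal and epithelial markers 0.35, lysosome and autophagy genes 0.05 and polyploidy response genes 0.03. With the GC trend removed and GC-matched lists, the KMT2A fusion targets (0.04) and the lysosome and autophagy genes (0.08) lay above their random ranges at 0.5 nM.

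**Figure D3:**
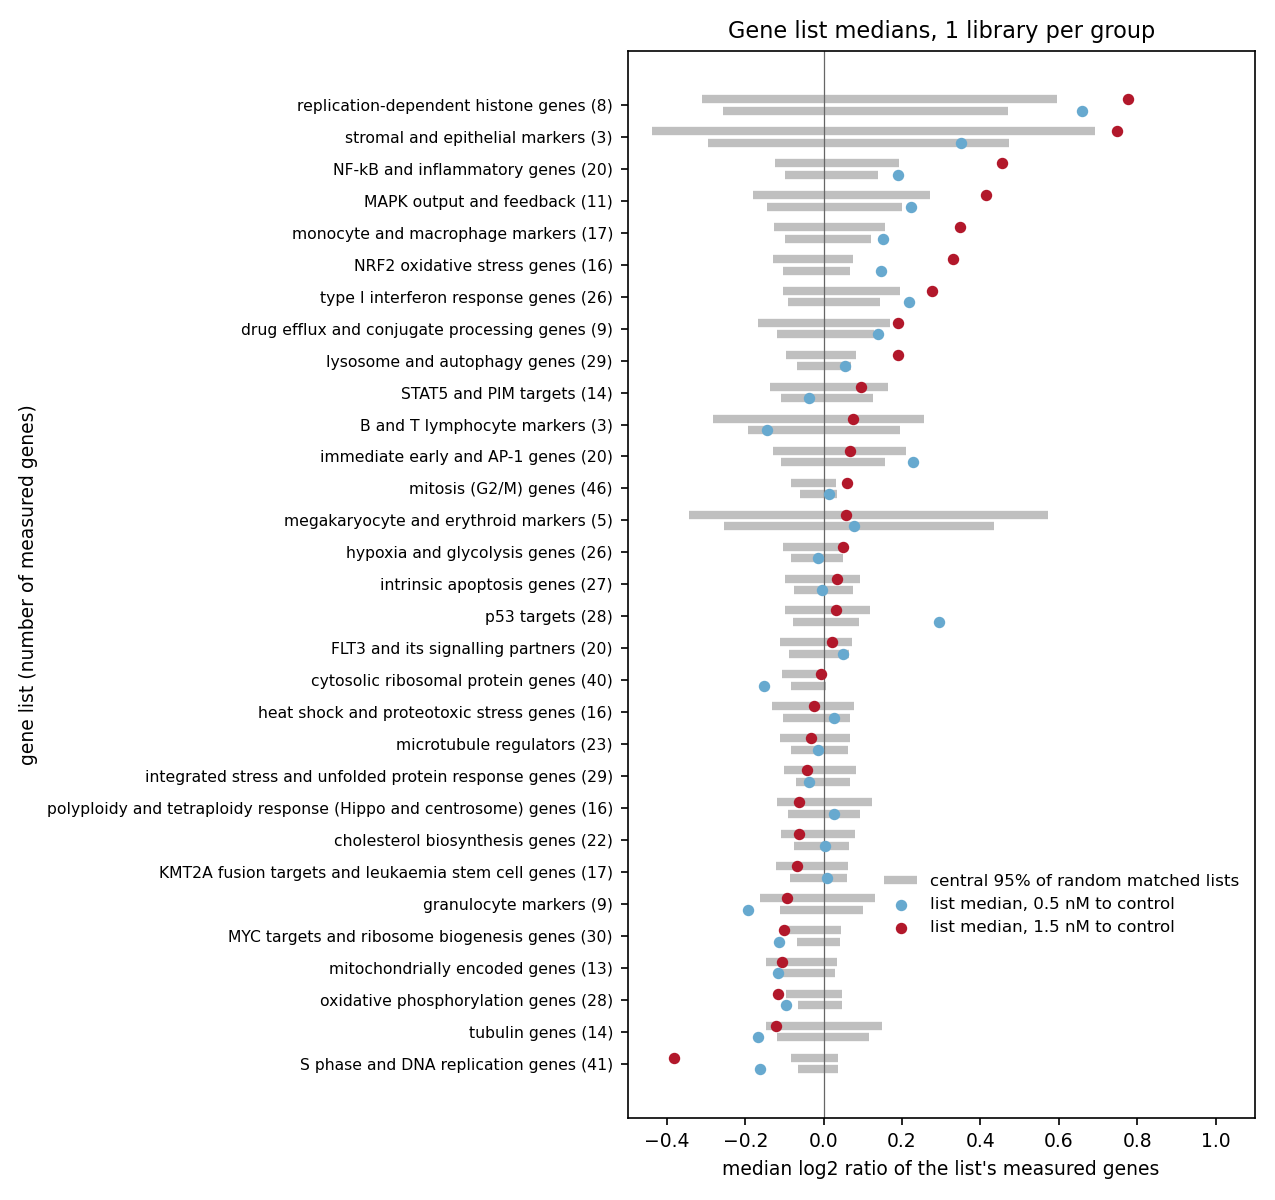
Median log2 ratio of the gene lists reported at 0.5 nM (blue) and 1.5 nM (red) to the control library, with the number of measured genes in brackets and grey bars for the central 95% of 10000 random lists matched on expression. S phase and DNA replication genes lie at -0.16 and -0.38, and p53 targets at 0.29 and 0.03.

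The libraries of the 2 doses were then compared directly. In the 1.5 nM library p53 targets were lower than at 0.5 nM, with a median of -0.25 (random range -0.09 to 0.10) and 23 of 28 below 0, and CDKN1A at -0.69 [-0.89, -0.49]. S phase and DNA replication genes had -0.22, with 38 of 41 below 0. NF-kB and inflammatory genes had 0.36, NRF2 oxidative stress genes 0.25, and monocyte and macrophage markers 0.21. HMOX1 had 1.65 [1.43, 1.90], C3 1.31 [0.96, 1.70] and OPLAH, an enzyme gene of the glutathione cycle, 1.09 [0.67, 1.56].

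A total of 54 genes were at least 2-fold higher and 56 at least 2-fold lower at 1.5 nM than at 0.5 nM, against simulated means of 5.44 and 5.19. IL4I1 had 1.00 and shares reads. Among the lower genes, IRS4 was at least 70.0-fold lower at the floor of 3 counts, AMOT had -2.22 and PLS3 -1.42. IRS4 belongs to the nearly missing group, for which RNA of another cell line in the other libraries stays open. AMOT and PLS3 also stood near the control at 0.5 nM, but lie outside that group, and the cause was not tested for them. FAM156A with -3.15 and SPDYE2 with -1.85 share reads with other genes. With whole-count genes alone the counts were 32 higher and 36 lower.

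Lysosome and autophagy genes at 1.5 nM against 0.5 nM had 0.13, drug efflux and conjugate processing genes 0.23, the cytosolic ribosomal protein genes 0.16, the mitosis genes 0.04 and the polyploidy response genes -0.13, each beyond the random range. The ratio between the treated libraries was higher for genes of higher GC content (Spearman 0.39 across genes). Other lists came inside the GC-matched range with the GC trend removed, and medians as normalised were -0.09 for intrinsic apoptosis genes, 0.07 for integrated stress and unfolded protein response genes, 0.20 for granulocyte markers and 0.22 for lymphocyte markers. Lists that came outside it were the immediate early and AP-1 genes with -0.17 and the mitochondrially encoded genes with 0.11.

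**Figure D4:**
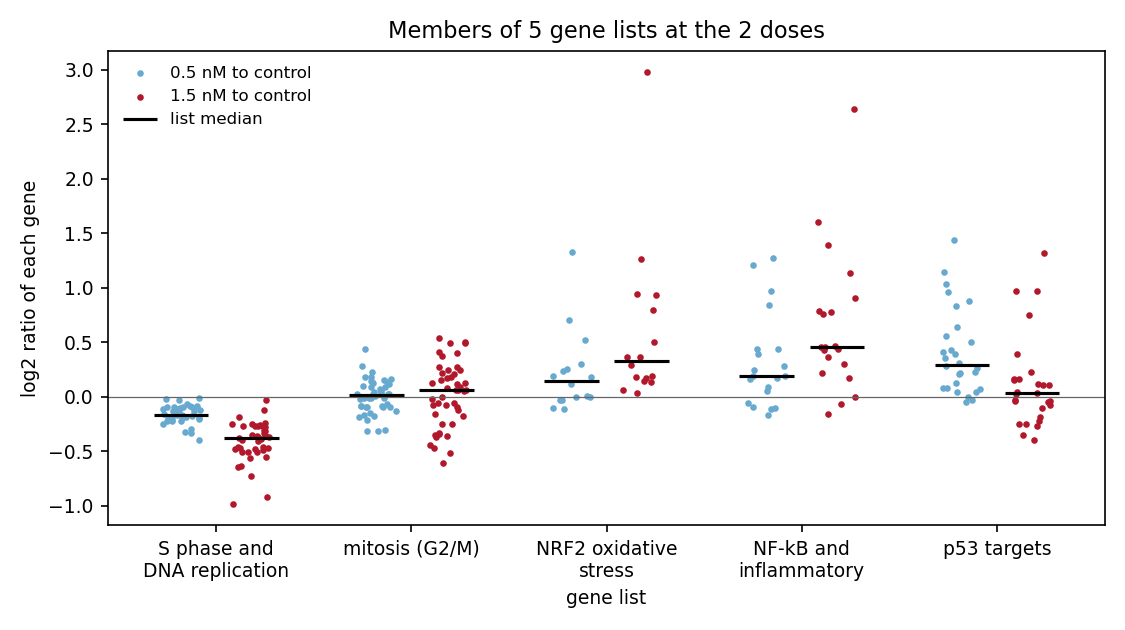
Log2 ratio of each measured member of 5 gene lists at 0.5 nM (blue) and 1.5 nM (red) to the control library, with a bar at each list's median. All 41 S phase and DNA replication genes lie below 0 at both doses, while 26 of 28 p53 targets lie above 0 at 0.5 nM and 15 of 28 at 1.5 nM.

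The last comparison asked how far the 2 doses shared genes. Of the genes at least 2-fold higher, 46 were so at both doses, among them HMOX1, C3, IGF1, CYP1B1, PHLDA1, SEMA6B, BTG2 and H2AC6. Of the 166 genes higher at 1.5 nM, 161 (97.0%) lay above 0 at 0.5 nM, and of the 65 lower genes 42 (64.6%) lay below 0. In simulated unchanged libraries the shared control alone gave 96.5% of 285 higher and 82.3% of 362 lower genes. Those simulated genes passed the threshold by counting error alone, unlike most of the observed ones. The shares therefore cannot tell agreement between the doses from the shared control. Of the lower genes, 6 were at least 2-fold lower at both doses, of which IGLL1 alone had a mean of 5 or more CPM. Independent lists of these sizes would share 0.88 higher and 0.15 lower genes, and simulated unchanged libraries against the same control shared at most 2 higher and 1 lower. With whole-count genes alone, 1 gene was lower at both doses, which equals that simulated highest. Across genes, the log2 ratios at the 2 doses correlated with Pearson's r = 0.55, against a simulated mean of 0.43 from the shared control alone, and their covariance was 0.0533 against 0.00873. The single control library could not be split, so part of the excess may come from it.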

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

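With 1 library per group, the planned DESeq2 and limma-voom tests, fits with 2 groups, replicate blocks, adjusted p thresholds, camera settings and runs without single libraries were not run. No paired analysis was possible because each group has 1 library. The settings on GC content, whole counts, counting intervals and nearly missing genes were chosen after seeing the data. Counts are given in the order 0.5 nM against control higher and lower, 1.5 nM against control higher and lower, and 1.5 nM against 0.5 nM higher and lower, where the values reported are 60, 26, 166, 65, 54 and 56. Genes higher and lower at both doses, reported as 46 and 6, follow in each case. With no expression minimum they were 535, 268, 722, 631, 540 and 869, then 203 and 121; this setting adds genes with few counts. With a minimum mean of 5 CPM, which leaves fewer genes, they were 15, 1, 42, 16, 4 and 13, then 13 and 1, and the lower gene at both doses was IGLL1. With log2(TPM + 1), which changes the scaling and the pseudocount together, they were 22, 12, 57, 20, 20 and 19, then 15 higher at both doses; the cause was not tested. With whole-count genes alone, lower genes were 8 at 0.5 nM, 36 at 1.5 nM and 36 between doses, higher genes between doses were 32, and 1 gene was lower at both doses. Under DESeq2 size factors, library totals, a prior count of 5, reduced totals, GC trend removal, counting intervals and without nearly missing genes, all 8 counts stayed within 1.5 times. Of the list medians, 1 of those beyond the random range turned: the MAPK output and feedback genes at 1.5 nM had -0.148 with a minimum mean of 5 CPM, against 0.41, because that setting drops members. Other list medians moved by more than the random lists' half-range, 8 with TPM, all at 0.5 nM, 2 with whole counts and 1 with the GC trend removed. With TPM the median of all genes at 0.5 nM was 0.0582, against 0.00173 in the main setting. Small list medians at 0.5 nM are therefore exposed to the choice of scaling. Lists beyond the random range at 0.5 nM, at 1.5 nM and between doses, reported as 16, 14 and 15, were 16, 14 and 15 with library totals and 19, 13 and 12 with the GC trend removed and GC-matched lists. Of 426 ratios of named genes, 85 moved beyond their counting interval with TPM, 43 with the GC trend removed, 10 with library totals and 2 with a prior count of 5. Depth limits genes near the minimum most, since a floor of 3 counts is 0.182 CPM in the 0.5 nM library.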

Other observations

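The gene groups of the first 2 paragraphs, and the tests of every pattern after them except the one on adherent cell markers, were chosen after the result was seen. All 7 measured MHC class II genes lay above 0 at 1.5 nM, with a median log2 ratio of 0.50 (random range -0.21 to 0.27). At 0.5 nM, 5 lay above and 2 below 0, and the median of 0.12 was inside its random range. HLA-DPA1 had 1.50, HLA-DRA 0.65 and the invariant chain gene CD74 0.45 at 1.5 nM. Targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds, had medians of 0.34 and 0.43 at the 2 doses over 7 genes. CYP1A1 had 0.98 and 1.66, CYP1B1 had 1.29 and 1.67, and the receptor's repressor gene AHRR had 0.34 and 0.37.

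Serine and asparagine synthesis genes stood lower. Of 10 measured genes, 9 lay below 0 at 1.5 nM, with a median of -0.30 (random range -0.15 to 0.11) and -0.24 at 0.5 nM. PHGDH had -0.78, PSAT1 -0.75, ALDH1L2 -0.70 and the asparagine synthetase gene ASNS -0.47 at 1.5 nM. Among 296 KEGG pathways with 15 or more measured genes, those with the lowest medians at 1.5 nM were DNA replication with -0.31, mismatch repair with -0.27 and homologous recombination with -0.17. The highest was ECM-receptor interaction with 0.44 over 31 genes, and complement and coagulation cascades had 0.32. In all, 105 pathways lay above and 32 below their random range at 1.5 nM; pathways share genes and are not independent.

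For the first pattern, the 50 genes nearly missing from the 1.5 nM library alone and led by IRS4, counting error or depth is argued against, since simulated unchanged libraries held at most 5 such genes. RNA of another cell line in the control and 0.5 nM libraries was tested with 40 markers of an embryonic kidney line and of adherent cells, listed before their values were seen. Of 23 with 10 or more counts, 9 (39.1%) lay below 0.5 times the mean of the other libraries, between the bounds set beforehand, and 6 of 1000 count-matched draws reached that share. All 9 are among the 15 markers under the expression minimum, a split made after seeing the values. None of the 8 that pass it in these MV-4-11 libraries, such as IGF2BP1 and FZD3, was as low. IGF2BP1 and FZD3 had 1990 and 489 counts in the 1.5 nM library itself, so a small foreign share could not show in them. The most abundant genes of the pattern stood at low levels, with IRS4 at 10.2 and 12.4 CPM. The median log2 ratio of the pattern's genes at 0.5 nM was 0.23. Each gene was chosen for 10 or more counts in that library, so this median cannot decide. Foreign RNA and a response to the drug that starts above 0.5 nM both stay open.

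The second pattern is the lower S phase and DNA replication genes at 1.5 nM. A GC trend between libraries is argued against, since the median was -0.38 with the trend removed, below the GC-matched random range that starts at -0.08. For a general decrease of highly expressed genes, the central 95% of random lists of like expression was -0.08 to 0.04, so such genes were not as low in general. That range is the one that first marked the list as lower, so it is no separate test. A lower share of cells in S phase after treatment is a candidate explanation, as a hypothesis, and it cannot be separated from differences between cultures with 1 library per group; DNA content measured in replicate cultures would test it.

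The third pattern is the lower TUBB and TUBA1B in the treated libraries, with a mean log2 ratio of -0.55 at 1.5 nM. A general decrease of the most abundant genes is argued against, since the other 256 genes with a mean of 500 or more CPM had a median of -0.06, and 2 of them were as low as TUBB. Reads split between tubulin copies are argued against by the sum of 10 alpha and beta tubulin genes, which had -0.49 at 1.5 nM and -0.31 at 0.5 nM. That sum rests mainly on TUBB and TUBA1B. The next most expressed copies were nearer the control at 1.5 nM, with TUBA1C at -0.37, TUBB4B at -0.13, TUBA4A at -0.06 and TUBB6 at 0.09. Removing the GC trend left the mean of TUBB and TUBA1B at -0.55. Decay of tubulin transcripts when free tubulin is plentiful, a known feedback, may account for it, as a hypothesis that was not tested here and that these data do not separate from differences between cultures; tubulin transcript half-lives in replicate cultures would test it.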
